A study of Homo sapiens with 9 samples.

How the data were processed

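Total RNA from 3 kinds of human cells was profiled on 9 expression arrays, 3 per kind. Per the labels, the induced pluripotent stem cell line GM25256*B (hiPSC) was the starting material, and it was differentiated into Leydig cell-like cells (hLLC) and, separately, into adrenal cell-like cells (hALC). The labels call the 3 arrays of each kind biological replicates and do not say whether they came from separate differentiations, so the p-values measure the spread between these arrays, which may be partly technical. Biotin-labelled cDNA was made with the Affymetrix WT plus protocol, per the labels' protocols. The deposited values are log2 expression per probe set, with 1 column per array, and RMA and Partek are named as the tools in the submitters' processing notes; their versions, the background setting and the annotation release are not given in the sources used here. RMA subtracts background, makes the arrays' distributions alike and combines probes into 1 value per probe set, so a change shared by most genes would be removed and differences of dim genes are compressed towards 0. No detection call per probe set was used here, so a level by itself does not show that a gene was expressed, and for arrays the number of arrays limits the precision.

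The values ran from 2.54 to 13.8 over the 9 arrays, with medians between 7.28 and 7.34. The columns were not identical in distribution: the interquartile range was 3.08, 3.25 and 3.10 in the hLLC arrays, 3.12, 3.25 and 3.25 in the hALC arrays and 3.32, 3.29 and 3.17 in the hiPSC arrays. No scan date or batch is given in the sources used here. Of 21448 probe sets, 17709 were paired with 1 gene symbol by the platform annotation, 0 with several, and 3739 are unnamed here. All 17709 matched a gene of the RefSeq table of assembly GRCh38.p14 through the Entrez ID, and 0 symbols had to be updated. The table was used for names alone and no coordinates are given, because no genome build is named for the array values. For the 20 symbols with more than 1 probe set, the brightest over the 9 arrays was taken, which left 17687 genes; in 7 of the 20 the probe sets differed in sign in at least 1 comparison. Genes with a near-identical copy (HSD3B1 with HSD3B2, CYP11B1 with CYP11B2, AKR1C1 with AKR1C2, and the HSPA1 pair) are uncertain, because probes of one can take up signal from the other. POU5F1, CYP21A2 and NR0B1 are not analysed here, since no probe set carries those names.

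A linear model with 1 mean per kind of cell was fitted to all 9 arrays with limma 3.58.1 (lmFit and eBayes, statmod 1.5.0) in R 4.3.3. Fitting the 3 groups together gives a shared estimate of the spread, with 12.5 degrees of freedom per gene after moderation. The comparisons were hLLC against hiPSC, hALC against hiPSC, and hLLC against hALC, each by limma's moderated test (2-sided) with Benjamini-Hochberg adjustment over the 17687 genes and a threshold of 0.05. Log2 changes are given with the fitted SE and, where useful, a 95% confidence interval. Group means carry the SD over 3 arrays. Genes were also counted with a filter of at least a 2-fold difference.

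The groups of arrays, the tests, the alternatives, 26 gene lists and the rule for naming genes were fixed before the data were examined, except where a text says otherwise. The lists held 436 entries, of which 378 were measured, and covered pluripotency, the steroidogenic machinery shared by testis and adrenal, Leydig cell genes, adrenal cortex genes, adrenogonadal transcription factors, cholesterol synthesis, cholesterol uptake, transport and storage, other steroid-metabolising enzymes, cAMP-responsive genes, the hedgehog pathway, WNT targets, retinoic acid response, HOX genes, mesenchyme and extracellular matrix, epithelial adhesion, cell division, stress and the unfolded protein response, senescence and inflammation, and markers of other cells the cultures could hold (neural cells, endoderm and liver, heart and skeletal muscle, endothelium, Sertoli and granulosa cells, adrenal medulla, kidney and germ cells). Each list was tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 26 lists. Camera was repeated with the correlation estimated from the residuals, and with fry, which tests whether a list's genes move one way on balance. Counts of list members that differed are given over all genes tested and adjusted over the list alone. The named genes are, per comparison, the 8 largest increases and the 8 largest decreases among genes past the threshold whose groups did not overlap, leaving out non-coding symbols, Y-linked genes and XIST; a fixed set (STAR, CYP11A1, HSD3B2, CYP17A1, CYP21A2, CYP11B1, CYP11B2, HSD17B3, LHCGR, INSL3, MC2R, MRAP, NR5A1, NR0B1, GATA4, POU5F1, NANOG, SOX2 and LIN28A); and up to 4 members per list with the largest changes past the threshold, or 2 as values where none passed.

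Changes from hiPSC in hLLC and hALC share the 3 hiPSC arrays. Unchanged groups were therefore simulated against shared controls 100 times, and the simulated correlation, covariance and same-sign share stand beside the observed ones. The alternatives were a replicate block, a fit of only the 2 groups compared, an intensity trend with robust moderation, no moderation, array weights, quantile normalization, centring each array on its median, leaving out the dimmest 33.3% of genes, all probe sets, the mean of a symbol's probe sets, a tested 2-fold threshold (treat), and leaving out each array in turn. A fit with each array's interquartile range as a covariate was added after seeing the data. The pipeline was tested on simulated data with the real genes and spreads. Of 17687 genes, 67, 67 and 66 were changed by log2 0.5, 1 and 2. Changes of log2 0.5 were recovered in 20.9% of cases for hLLC against hiPSC, 29.9% for hALC against hiPSC and 26.9% for hLLC against hALC. At log2 1 the shares were 95.5%, 98.5% and 98.5%, and at log2 2 they were 100% in each. Far fewer genes were changed here than differed in the real data, which makes the adjusted threshold stricter. These shares therefore do not give the recovery in the real comparisons. False calls made up 6.49%, 5% and 2.6% of all calls in the 3 comparisons, the first above the nominal 5%.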

Results

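The transcriptomes of human Leydig cell-like cells (hLLC), human adrenal cell-like cells (hALC) and the induced pluripotent stem cell line from which both were made (hiPSC) were measured on expression arrays. Leydig cells are the androgen-producing cells of the testis, and the adrenal cortex makes cortisol, aldosterone and weak androgens. Each kind of cell was represented by 3 arrays, and 17687 named genes were tested on the log2 RMA scale. With 3 arrays in a group, the number of arrays limited the precision: the median SE of a log2 difference was 0.14.

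Arrays of one kind lay close together. The first principal component held 77.7% of the variance and set the hiPSC arrays apart from the other 6, and the second held 13.7% and separated hLLC from hALC. Correlations across genes ran from 0.987 to 0.994 within a group, from 0.967 to 0.975 between hLLC and hALC arrays, from 0.877 to 0.892 between hLLC and hiPSC, and from 0.882 to 0.89 between hALC and hiPSC. Genes are not independent replicates, so these correlations are descriptions and carry no test.

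**Figure D1:**
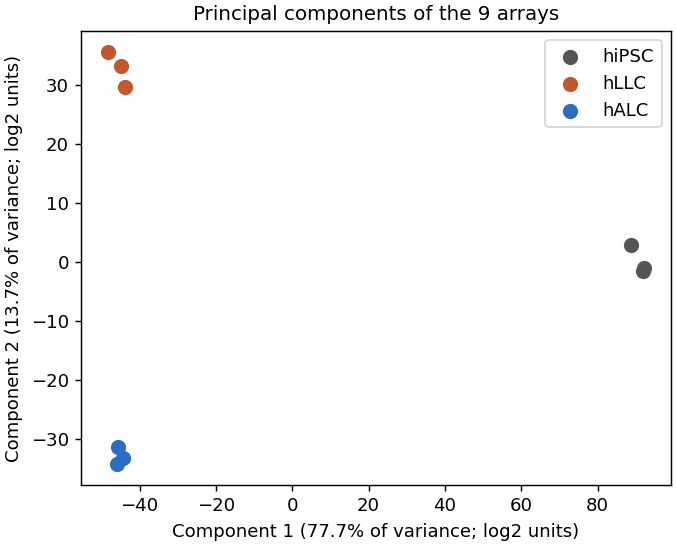
Principal components of the 9 arrays, with component 1 (77.7% of the variance) on the horizontal axis and component 2 (13.7%) on the vertical axis, both in log2 units; each point is an array. The 3 hiPSC arrays lie between 88.77 and 92.1 on component 1 and the other 6 between -48.22 and -43.73, while component 2 parts hLLC (29.75 to 35.68) from hALC (-34.35 to -31.45).

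The first comparison asked what distinguished Leydig cell-like cells from the stem cells they came from. CYP17A1, an enzyme on the way to androgens and cortisol, was 62-fold higher in hLLC, at 11.54 ± 0.07 against 5.58 ± 0.09 on the log2 scale (SD, n = 3 each; log2 change 5.95, SE 0.13, 95% interval 5.66 to 6.24, adjusted p = 3.68e-12). NR5A1, the nuclear receptor that directs steroidogenic differentiation, rose 27.1-fold; the labels do not say whether it was introduced into the cells from outside. LHCGR, the receptor through which luteinising hormone acts on Leydig cells, rose 3.36-fold. Mesenchyme and extracellular matrix genes rose in 24 of 25 cases, and pluripotency genes fell in 20 of 24, epithelial adhesion genes in 11 of 15 and cell division genes in 29 of 29. The cell division list lost its call at adjusted p = 0.0597 with an estimated correlation. In all, 8990 of 17687 genes (50.8%) differed by limma at an adjusted p under 0.05, 4390 higher and 4600 lower in hLLC, and 3556 of them differed at least 2-fold (1630 higher, 1926 lower).

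The largest increases in hLLC were not in steroidogenic genes. PRL, which encodes the hormone prolactin, went from 3.75 ± 0.12 to 11.74 ± 0.19, a 254-fold rise (log2 7.99, SE 0.13, adjusted p = 5.24e-13). It was followed by SCG2, a secretogranin (202-fold), SV2C, a synaptic vesicle protein (191-fold), and IGFBP3, a binding protein of insulin-like growth factors (161-fold). Next came ITGA11, a collagen-binding integrin (155-fold), ANXA1, an annexin (138-fold), NT5E, a cell surface enzyme used as a mesenchymal marker (137-fold), and LUM, a matrix proteoglycan (128-fold). The largest decrease was in ESRP1, a splicing factor of epithelial cells, which was 306-fold lower (log2 -8.26, SE 0.13, adjusted p = 5.24e-13). It was followed downwards by L1TD1 (178-fold), USP44 (121-fold), NANOG (103-fold), DNMT3B (90-fold), CRIPTO (78.8-fold), NR5A2 (72.9-fold) and EPCAM (69.2-fold).

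Within the steroidogenic machinery, 5 of 9 measured members rose and 1 fell in hLLC (6 and 1 adjusted over the list alone), with a median log2 change of 1.03 (camera adjusted p = 0.0188). The call was lost with an estimated correlation (adjusted p = 0.128 with an estimated correlation) and without the dimmest genes (adjusted p = 0.0959), over a range of 0.00174 to 0.128 in 17 alternatives. Beside CYP17A1 the increases were in HSD3B2 (8.87-fold, log2 3.15, SE 0.13) and HSD3B1 (4.39-fold), which encode steroid dehydrogenases. Smaller ones were in CYP11A1, which cleaves the cholesterol side chain (2.64-fold, log2 1.40, SE 0.17, adjusted p = 1.49e-05) and STAR, which brings cholesterol into mitochondria (2.05-fold, log2 1.03, SE 0.13, adjusted p = 1.47e-05). CYB5A, a cofactor of the CYP17A1 lyase reaction, fell 2.75-fold. HSD3B1 and HSD3B2 are near-identical and cannot be fully separated on the array.

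Of 15 measured Leydig cell genes, 10 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.00119; adjusted p = 0.0975 with an estimated correlation). DLK1, a membrane protein of immature Leydig cells, rose 93.2-fold, TCF21 14.8-fold, CALB2 5.9-fold and LHCGR from 4.62 ± 0.23 to 6.37 ± 0.57 (log2 1.75, SE 0.24, adjusted p = 3.39e-05). INSL3, a peptide hormone of Leydig cells, differed by log2 0.39 (SE 0.15, adjusted p = 0.0464). That call ended in 7 of 16 alternatives, whose adjusted p ran from 0.0155 to 0.369. With array spread as a covariate the log2 change was 0.18, and it was 0.37 without hLLC array 1, 0.29 without hLLC array 3, 0.26 without hiPSC array 1 and 0.40 without hiPSC array 2. HSD17B3, the testicular enzyme that makes testosterone, lay at 4.78 ± 0.33 against 4.56 ± 0.12 and did not pass (log2 0.22, SE 0.15, adjusted p = 0.248).

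Among 16 measured adrenal cortex genes, 5 rose and 4 fell (6 and 4 adjusted over the list alone), and the list did not pass camera, which sets a list against other genes (adjusted p = 0.542), but rose with fry, which does not (adjusted p = 0.00786). The angiotensin receptor gene AGTR1 rose 13.2-fold and DAB2 10.9-fold, while VSNL1 fell 18.3-fold and TSPAN12 5-fold. CYP11B1, which completes cortisol synthesis, differed by log2 0.24 (SE 0.19, adjusted p = 0.318), CYP11B2, which makes aldosterone, by 0.27 (SE 0.14, adjusted p = 0.123) and MRAP, the accessory protein of the corticotropin receptor, by 0.30 (SE 0.12, adjusted p = 0.0586). MC2R, the corticotropin receptor itself, was higher by log2 0.60 (SE 0.19, adjusted p = 0.0183), a call that ended in 3 of 15 alternatives (0.0065 to 0.0952). These were the fits without hLLC array 2 (log2 0.40, adjusted p = 0.0796), without hiPSC array 2 (log2 0.41, adjusted p = 0.0952) and without moderation (adjusted p = 0.0838). Adrenogonadal transcription factors were split, with 4 of 13 higher and 4 lower on either adjustment. The median was -0.23, the mean 0.01, and the camera adjusted p = 0.959. NR5A1 and TCF21 rose, whereas NR5A2 fell 72.9-fold and GATA4, a factor of gonadal and other mesoderm, fell 4.76-fold (log2 -2.25, SE 0.20).

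In cholesterol synthesis, 12 of 16 fell and 1 rose, with the same counts adjusted over the list alone (median -0.59, camera adjusted p = 3.08e-04, held with an estimated correlation). The decreases were led by HMGCS1 (4-fold), HSD17B7 (3.07-fold), EBP (2.98-fold) and SQLE (2.88-fold). In cholesterol uptake, transport and storage, 6 of 12 rose and 2 fell (7 and 2 adjusted over the list alone; median 0.81, camera adjusted p = 0.0342; adjusted p = 0.192 with an estimated correlation). SOAT1, which esterifies cholesterol (3.84-fold), led the increases with SCARB1, a lipoprotein receptor (3.27-fold). The call for this uptake list was also lost without the dimmest genes (adjusted p = 0.0592). Other steroid-metabolising enzymes, 9 of 19 higher and 2 lower (9 and 3 adjusted over the list alone), did not pass camera (adjusted p = 0.0915) but rose with fry (adjusted p = 2.91e-04). HSD17B2 rose 8.67-fold and HSD11B2 fell 3.47-fold.

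Pluripotency genes fell in 20 of 24 cases, with the same count adjusted over the list alone and none higher (median -2.63, camera adjusted p = 4.75e-14). Beside NANOG, LIN28A fell 17.3-fold and SOX2 5.1-fold. All 29 cell division genes fell on either adjustment (median -2.41, camera adjusted p = 4.07e-19; adjusted p = 0.0597 with an estimated correlation), among them BUB1B (12.6-fold), BUB1 (9.28-fold) and KIF20A (7.98-fold). In epithelial adhesion 11 of 15 fell and 2 rose on either adjustment (median -2.77, camera adjusted p = 9.92e-07), with CDH1, the epithelial cadherin, 41.9-fold lower. In mesenchyme and extracellular matrix 24 of 25 rose on either adjustment (median 2.96, camera adjusted p = 9.28e-16), including POSTN (71.9-fold), ACTA2 (52.3-fold) and LOX (51.7-fold). HOX genes rose in 19 of 23 cases, none falling, on either adjustment (median 1.36, camera adjusted p = 2.1e-08), with HOXD10 15.1-fold and HOXC10 13.1-fold higher.

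In cAMP-responsive genes 10 of 15 rose and 1 fell on either adjustment (camera adjusted p = 0.00249; adjusted p = 0.374 with an estimated correlation), with PDE7B 42.2-fold and NR4A3 12.8-fold higher and PDE3B 10.5-fold lower. Among WNT targets 7 of 13 rose and 1 fell (8 and 1 adjusted over the list alone; camera adjusted p = 0.0175; adjusted p = 0.0968 with an estimated correlation), led by TNFRSF19 (11.2-fold), DKK1 (6.75-fold) and, downwards, LGR5 (6.36-fold). Stress and unfolded protein response genes rose in 9 of 15 cases and fell in 1 (10 and 1 adjusted over the list alone; camera adjusted p = 0.00451; adjusted p = 0.269 with an estimated correlation), with HMOX1 7.84-fold and HERPUD1 7.24-fold higher. In senescence and inflammation 13 of 16 rose and 1 fell (13 and 2 adjusted over the list alone; camera adjusted p = 6.1e-05). The moving members were led by the growth factor binding proteins IGFBP3, IGFBP7 (102-fold) and IGFBP5 (24.9-fold) and by the lamin gene LMNB1, which fell 14.1-fold. Without moderation of the spread, the cAMP and stress calls ended at adjusted p = 0.0528 and 0.0579.

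Hedgehog genes (5 of 13 higher, 3 lower on either adjustment, camera adjusted p = 0.611; PTCH1 5.36-fold lower, BOC 2.23-fold higher) and retinoic acid response genes (3 of 8 higher, 2 lower, or 5 and 2 adjusted over the list alone, camera adjusted p = 0.537; CYP26A1 36.4-fold lower, RARB 10.1-fold higher) did not pass camera but rose with fry (adjusted p = 2.56e-04 and 0.00264). Of 8 lists of other cell types 0 passed camera and 7, all but kidney, passed fry. With fry endoderm and liver and germ cell genes fell, and the other passing lists rose. Of neural genes 4 of 9 rose and 1 fell (camera adjusted p = 0.295), led by STMN2 (37.2-fold), and of Sertoli and granulosa genes 6 of 11 rose and 3 fell (0.361), with INHBA 35.2-fold higher and CLDN11 15.9-fold lower. For the endoderm and liver list the counts were 1 of 10 higher and 3 lower (0.347; FOXA2 8.57-fold lower), for heart and skeletal muscle 2 of 11 and 2 (0.412; ACTC1 31.3-fold higher) and for endothelium 3 of 12 and 1 (0.327; ENG 8.73-fold higher). Adrenal medulla genes gave 3 of 10 higher and 1 lower (0.412; CHGB 1.76-fold higher, lost without moderation at adjusted p = 0.0571, the highest of 15 alternatives from 4.12e-04), kidney genes 1 of 9 and 1 (0.658; LHX1 11-fold lower) and germ cell genes 1 of 10 and 2 (0.658; DPPA3 2.19-fold lower). The only germ cell gene higher, NANOS3 (log2 0.46, adjusted p = 0.0264), lost its call in 6 of 15 alternatives. The only adrenal medulla gene lower, SLC18A2 (log2 -0.39, adjusted p = 0.0268), lost its call in 7 of 15. Adjusted over the list alone the counts of these 8 lists were the same except in heart and skeletal muscle, where 1 rose. The kidney median of 0.26 and mean of -0.10 differed in sign, as did those of the germ cell list (0.01 and -0.12).

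**Figure D2:**
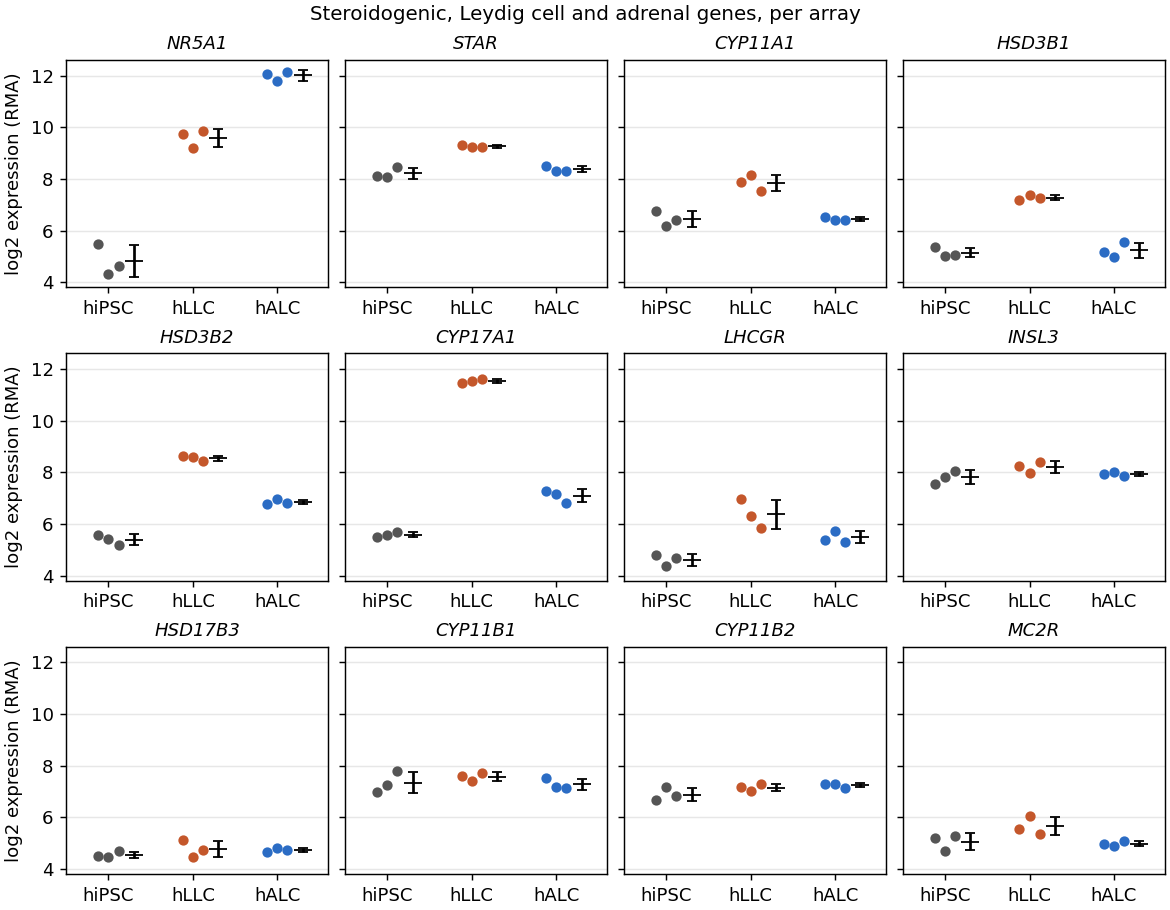
Log2 RMA expression of 12 steroidogenic, Leydig cell and adrenal genes in the 9 arrays, with each array as a coloured point and the mean ± SD of each group in black (n = 3). CYP17A1 stands at 11.54 in hLLC, 7.09 in hALC and 5.58 in hiPSC, whereas NR5A1 is highest in hALC (12.0 against 9.58 in hLLC and 4.82 in hiPSC).

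Adrenal cell-like cells were set against the same stem cells. NR5A1 rose 145-fold, from 4.82 ± 0.61 to 12.0 ± 0.20 (SD, n = 3 each; log2 change 7.18, SE 0.26, 95% interval 6.62 to 7.74, adjusted p = 1.3e-10), and was among the 8 largest increases. The steroidogenic enzymes moved less: CYP17A1 rose 2.84-fold (log2 1.51, SE 0.13, adjusted p = 7.5e-07) and HSD3B2 2.75-fold (log2 1.46, SE 0.13, adjusted p = 6.58e-07), while STAR differed by log2 0.15 (SE 0.13, adjusted p = 0.349) and CYP11A1 by -0.00 (SE 0.17, 95% interval -0.38 to 0.37, adjusted p = 0.989). Mesenchyme and extracellular matrix genes rose in 23 of 25 cases, and decreases took in 20 of 24 pluripotency, 14 of 15 epithelial adhesion, 29 of 29 cell division and 15 of 16 cholesterol synthesis genes. Of these lists, cell division lost its call at adjusted p = 0.15 with an estimated correlation. Altogether 8732 of 17687 genes (49.4%) differed by limma, 4082 higher and 4650 lower in hALC, with 3459 at least 2-fold apart (1585 higher, 1874 lower).

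The largest increase in hALC was in IL7R, an interleukin receptor gene, which went from 4.28 ± 0.34 to 11.72 ± 0.38 (174-fold, log2 7.44, SE 0.20, adjusted p = 9.52e-12). It was followed by POSTN, a matrix protein (173-fold), NT5E (165-fold), MMP13, a collagenase (160-fold), MGP, an inhibitor of calcification (160-fold), COL6A3, a chain of collagen VI (152-fold), and IGFBP3 (146-fold). The decreases were led by ESRP1 (270-fold, log2 -8.07, SE 0.13, adjusted p = 3.37e-13), CST1, a cystatin (242-fold), MAL2 (159-fold), USP44 (149-fold), EPCAM (143-fold), CRIPTO (138-fold), NTS, the neurotensin gene (125-fold), and L1TD1 (121-fold).

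The steroidogenic machinery did not pass camera in hALC, with 3 of 9 higher and 1 lower on either adjustment (median 0.15, adjusted p = 0.413), but rose with fry (adjusted p = 0.00309). TSPO, a mitochondrial membrane protein, rose 1.94-fold and CYB5A fell 1.96-fold. Leydig cell genes rose in 10 of 15 cases and fell in 2 on either adjustment (median 0.60, camera adjusted p = 0.00584; adjusted p = 0.18 with an estimated correlation). DLK1 was 61.3-fold higher, PDGFRA 6.62-fold, and PRLR, the prolactin receptor, 5.52-fold. LHCGR was 1.82-fold higher (log2 0.86, SE 0.24, adjusted p = 0.008), which was lost without moderation (adjusted p = 0.0655; 0.001 to 0.0655 over 15 alternatives). INSL3 (log2 0.12, SE 0.15, adjusted p = 0.562) and HSD17B3 (0.19, SE 0.15, adjusted p = 0.323) did not pass.

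Adrenal cortex genes were split in hALC, with 6 of 16 higher and 4 lower on either adjustment (camera adjusted p = 0.71). AGTR1 rose 22-fold and DAB2 9.56-fold, and VSNL1 fell 22.2-fold and TSPAN12 4.53-fold. CYP11B1 (log2 -0.06, SE 0.19, adjusted p = 0.812) and MC2R (-0.08, SE 0.19, adjusted p = 0.772) did not pass. CYP11B2 differed by log2 0.36 (SE 0.14, adjusted p = 0.0471), which ended in 11 of 16 alternatives (adjusted p from 0.0101 to 0.19), including the fits without hALC array 1 (log2 0.33), hALC array 2 (0.33), hALC array 3 (0.40), hiPSC array 1 (0.25) and hiPSC array 3 (0.32). MRAP differed by log2 0.37 (SE 0.12, adjusted p = 0.0227), which ended in 4 of 15 (0.00594 to 0.077), including those without hALC array 3 (log2 0.34), hiPSC array 2 (0.37) and hiPSC array 3 (0.33). Of the adrenogonadal transcription factors, 3 of 13 rose and 5 fell (3 and 6 adjusted over the list alone). The list did not pass camera (adjusted p = 0.546) but fell with fry (adjusted p = 0.00167). Besides NR5A1 and TCF21 (3.74-fold higher) the largest changes were decreases of NR5A2 (59-fold), GATA4 (4.39-fold) and GATA6 (4.06-fold).

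Cholesterol synthesis genes fell in 15 of 16 cases in hALC, and in 16 adjusted over the list alone (median -1.25, camera adjusted p = 1.46e-06), led by HMGCS1 (5.26-fold), DHCR7 (4.58-fold), HSD17B7 (3.54-fold) and TM7SF2 (3.33-fold). Cholesterol uptake genes were split, 5 of 12 higher and 4 lower (5 and 5 adjusted over the list alone, camera adjusted p = 0.71). With fry the uptake list rose (adjusted p = 0.0184), and ABCA1 was 5.6-fold higher and VLDLR 3.92-fold lower. Other steroid-metabolising enzymes were split too, 7 of 19 higher and 5 lower on either adjustment (camera adjusted p = 0.71), with HSD17B2 4.82-fold higher and CYP1B1 3.95-fold lower.

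Pluripotency genes fell in 20 of 24 cases on either adjustment (median -2.91, camera adjusted p = 3.31e-14), with NANOG 98.6-fold, LIN28A 19.3-fold and SOX2 3.32-fold lower. In epithelial adhesion 14 of 15 fell on either adjustment (median -1.91, camera adjusted p = 1.42e-10), with CDH1 47.2-fold and OCLN, a tight junction protein, 37.7-fold lower. All 29 cell division genes fell on either adjustment (median -1.25, camera adjusted p = 2.46e-12; adjusted p = 0.15 with an estimated correlation), among them BUB1B (4.34-fold) and HMMR (3.8-fold). In mesenchyme and extracellular matrix 23 of 25 rose on either adjustment (median 3.22, camera adjusted p = 4.91e-18), with LUM 110-fold and ACTA2 45.5-fold higher. HOX genes rose in 19 of 23 cases on either adjustment (median 1.48, camera adjusted p = 2.95e-08), with HOXD10 21.2-fold and HOXC10 12.2-fold higher.

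Among the signalling lists, cAMP-responsive genes rose in 11 of 15 cases and fell in 2 (11 and 3 adjusted over the list alone; camera adjusted p = 0.00568; adjusted p = 0.588 with an estimated correlation, and 0.0792 without moderation), with PDE7B 38.6-fold, PDE4D 18.4-fold and RGS2 7.11-fold higher. Senescence and inflammation genes rose in 9 of 16 cases and fell in 3 on either adjustment (camera adjusted p = 0.00289; adjusted p = 0.101 with an estimated correlation), led by IGFBP3, IGFBP7 (89.8-fold), IGFBP5 (22.8-fold) and the collagenase MMP1 (21-fold). Hedgehog genes, 5 of 13 higher and 2 lower on either adjustment, did not pass camera (adjusted p = 0.399) but rose with fry (adjusted p = 5.17e-06). HHIP, which binds hedgehog ligands, rose 10.2-fold and PTCH1 fell 3.09-fold. WNT targets, 4 of 13 higher and 4 lower (4 and 5 adjusted over the list alone), gave a median of -0.17, a mean of 0.33 and a camera adjusted p = 0.77. With fry the WNT list rose (adjusted p = 1.23e-05). TNFRSF19 rose 9.09-fold and LGR5 fell 4.45-fold. Retinoic acid response genes, 3 of 8 higher and 2 lower on either adjustment, gave a median of 0.05, a mean of -0.32 and a camera adjusted p = 0.95. With fry this list fell (adjusted p = 0.00249). CYP26A1 was 33-fold lower and RARB 6.19-fold higher. Stress genes rose in 7 of 15 cases and fell in 1 on either adjustment (camera adjusted p = 0.143, but 0.0045 with fry), with HERPUD1 7.46-fold higher and ASNS 3.94-fold lower.

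Of the lists of other cell types in hALC 0 of 8 passed camera, and 6 passed fry, all but adrenal medulla and Sertoli and granulosa cells. With fry endoderm and liver, kidney and germ cell genes fell, and the other passing lists rose. Neural genes gave 4 of 9 higher and 2 lower (camera adjusted p = 0.384), led by STMN2 (70.6-fold), and Sertoli and granulosa genes 3 of 11 and 2 (0.71; median 0.15, mean -0.04), with INHBA 35.7-fold higher and CLDN11 18.6-fold lower. Endoderm and liver genes gave 1 of 10 higher and 4 lower (0.509; FOXA2 7.76-fold lower), heart and skeletal muscle 1 of 11 and 2 (0.546; ACTC1 4.4-fold higher) and endothelium 2 of 12 and 1 (0.38; ENG 10.9-fold higher). In the adrenal medulla list 1 of 10 was higher and 2 lower (0.692; CHGB 1.86-fold higher), in the kidney list 1 of 9 and 3 (0.509; LHX1 11.9-fold lower) and in the germ cell list 1 of 10 and 4 (0.463; KIT 43.5-fold lower). Adjusted over the list alone, 5 neural genes and 2 germ cell genes rose and 1 medulla gene fell, with the other counts as given.

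The 2 differentiated products were then compared directly. CYP17A1 was 21.8-fold higher in hLLC, at 11.54 ± 0.07 against 7.09 ± 0.25 (SD, n = 3 each; log2 difference 4.45, SE 0.13, 95% interval 4.16 to 4.74, adjusted p = 8.65e-10). NR5A1 was 5.35-fold lower in hLLC, at 9.58 ± 0.35 against 12.0 ± 0.20 (log2 -2.42, SE 0.26, adjusted p = 2.18e-05). In hLLC 28 of 29 cell division genes and 10 of 25 mesenchyme and matrix genes were lower than in hALC, and 5 of 16 cholesterol synthesis and 4 of 12 cholesterol uptake genes were higher. These 4 lists passed with the preset correlation and not with an estimated correlation (adjusted p = 0.156 for the first 3 and 0.175 for uptake). By limma 3656 of 17687 genes (20.7%) differed, 1843 higher and 1813 lower in hLLC, and 914 at least 2-fold (455 higher, 459 lower).

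KIT, the receptor of stem cell factor, showed the largest excess in hLLC (37.3-fold, 9.71 ± 0.02 against 4.49 ± 0.24, log2 5.22, SE 0.15, adjusted p = 8.65e-10). After CYP17A1 came MAL2 (18.3-fold), WNT2B, a WNT ligand (17-fold), CYP24A1, which degrades active vitamin D (16.5-fold), PLCB4, a phospholipase (12-fold), MLIP (10.1-fold) and SELENOP, a selenium carrier (8.94-fold). An excess over hALC need not be a gain over hiPSC. KIT lay at 9.93 in hiPSC, near its hLLC level. MAL2 lay at 11.88 in hiPSC, above its levels in hLLC (8.76) and hALC (4.56). The largest excess in hALC was in MMP13, at 10.85 ± 0.17 against 3.81 ± 0.27 in hLLC (131-fold, log2 -7.04, SE 0.15, adjusted p = 4.14e-11), then OGN, a small matrix proteoglycan (51.4-fold), MGP (24.2-fold), the chemokine gene CXCL5 (18.6-fold), COL10A1, collagen X (15.5-fold), HHIP (14.6-fold), CRYBG1 (14.3-fold) and the chemokine gene CXCL13 (12.8-fold).

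In the steroidogenic machinery 5 of 9 members were higher and 1 lower in hLLC on either adjustment (median 0.88, camera adjusted p = 0.00523; adjusted p = 0.156 with an estimated correlation). HSD3B1 was 4.12-fold higher (log2 2.04, SE 0.15), HSD3B2 3.23-fold (log2 1.69, SE 0.13), CYP11A1 2.65-fold (log2 1.41, SE 0.17, adjusted p = 7.27e-05) and STAR 1.84-fold (log2 0.88, SE 0.13, adjusted p = 2.75e-04). Cholesterol synthesis genes were higher in hLLC in 5 of 16 cases and lower in 0 (6 and 0 adjusted over the list alone; median 0.24, camera adjusted p = 0.0109; adjusted p = 0.156 with an estimated correlation), led by TM7SF2 (2.34-fold) and SC5D (2.24-fold). Of the uptake, transport and storage genes 4 of 12 were higher and 1 lower on either adjustment (camera adjusted p = 0.0169; adjusted p = 0.175 with an estimated correlation), with SCARB1 6.02-fold, STARD4 2.69-fold and VLDLR 2.57-fold higher. Other steroid-metabolising enzymes had 7 of 19 higher and 3 lower on either adjustment (camera adjusted p = 0.0492; adjusted p = 0.275 with an estimated correlation), with CYP1B1 7.56-fold and AKR1C1 2.84-fold higher. The call of that last list ended in 8 of 17 alternatives (0.0279 to 0.275), including those without hLLC array 2 (adjusted p = 0.0677), hLLC array 3 (0.0557), hALC array 1 (0.0836) or hALC array 2 (0.0521).

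Leydig cell genes differed in both directions, 6 of 15 higher in hLLC and 4 lower (7 and 4 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.198) but was higher in hLLC with fry (adjusted p = 0.00623). TCF21 was 3.95-fold and CALB2 3.88-fold higher in hLLC, and PRLR 3.56-fold and PDGFRA 2.19-fold higher in hALC. LHCGR was higher in hLLC by log2 0.89 (SE 0.24, adjusted p = 0.0173), which ended in 4 of 15 alternatives (0.00295 to 0.114), including those without hLLC array 1 (log2 0.59), hALC array 1 (0.84) or hALC array 3 (0.80). INSL3 (log2 0.28, SE 0.15, adjusted p = 0.237) and HSD17B3 (0.03, SE 0.15, adjusted p = 0.919) did not pass. Of the adrenal cortex genes 2 of 16 were higher in hLLC and 1 lower on either adjustment (camera adjusted p = 0.624). With fry the adrenal cortex list was higher in hLLC (adjusted p = 0.0435). GSTA1 was 2.46-fold higher in hLLC and MC2R 1.6-fold (log2 0.67, SE 0.19, adjusted p = 0.0235), the latter lost in 4 of 15 alternatives (0.0133 to 0.113), including those without hLLC array 2 (log2 0.47), hALC array 1 (0.67) or hALC array 2 (0.64). CYP11B1 (log2 0.30, SE 0.19, adjusted p = 0.299), CYP11B2 (-0.09, SE 0.14, adjusted p = 0.712) and MRAP (-0.07, SE 0.12, adjusted p = 0.732) did not pass. Adrenogonadal transcription factors were higher in hLLC in 6 of 13 cases and lower in 1 on either adjustment (camera adjusted p = 0.148). With fry this list was higher in hLLC (adjusted p = 0.00685). CITED2 was 1.61-fold higher, and GATA4 differed by log2 -0.12 (SE 0.20, adjusted p = 0.742).

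Cell division was the list with the smallest p. In hLLC 28 of 29 members were lower than in hALC on either adjustment (median -1.18, camera adjusted p = 2.29e-25; adjusted p = 0.156 with an estimated correlation), among them KIF11 (3.63-fold), CDK1 (3.23-fold), BUB1B (2.9-fold) and TOP2A (2.8-fold). Mesenchyme and matrix genes were lower in hLLC in 10 of 25 cases and higher in 1 (11 and 3 adjusted over the list alone; median -0.30, camera adjusted p = 0.00192; adjusted p = 0.156 with an estimated correlation), led by COL6A3 (2.99-fold), COL6A2 (2.86-fold) and PDGFRB (2.44-fold). Epithelial adhesion genes were higher in hLLC in 5 of 15 cases and lower in 1 (6 and 2 adjusted over the list alone; camera adjusted p = 0.0321; adjusted p = 0.305 with an estimated correlation), with KRT18 6.43-fold, OCLN 3.05-fold and KRT8 2.52-fold higher. The arrays' spread moved in part with the groups, and with it as a covariate the epithelial call ended (adjusted p = 0.115; 0.00557 to 0.305 over 17 alternatives).

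WNT targets were higher in hLLC in 5 of 13 cases and lower in 0 (6 and 1 adjusted over the list alone; camera adjusted p = 0.0109; adjusted p = 0.156 with an estimated correlation), with AXIN2, a feedback target of WNT signalling, 3.24-fold and BAMBI 2.69-fold higher. Retinoic acid response genes were higher in 3 of 8 cases on either adjustment (camera adjusted p = 0.0321; adjusted p = 0.17 with an estimated correlation), with ALDH1A1, which makes retinoic acid, 2.89-fold, CRABP2 1.82-fold and RARB 1.62-fold higher. The call ended without hALC array 2 (adjusted p = 0.0521) and without moderation (0.0537), over a range of 0.0247 to 0.17. In the stress list 6 of 15 were higher and 0 lower on either adjustment (camera adjusted p = 0.014; adjusted p = 0.399 with an estimated correlation), with HMOX1 3.48-fold and ATF3 3.23-fold higher. Without hLLC array 3 the adjusted p was 0.0748 (0.00423 to 0.399 over 17 alternatives). cAMP-responsive genes were split, 3 of 15 each way on either adjustment (camera adjusted p = 0.663), with DUSP1 2.52-fold higher in hLLC and RGS2 3.93-fold lower.

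The lists that follow did not pass camera between the products, but hedgehog (lower in hLLC), pluripotency, heart and skeletal muscle, Sertoli and granulosa, kidney and germ cell genes (higher) passed fry, at adjusted p from 6.67e-05 to 0.0189. Pluripotency genes gave 2 of 24 higher and 3 lower in hLLC (camera adjusted p = 0.663), with LIN28B 2.4-fold higher, NANOG at log2 -0.07 (SE 0.12, adjusted p = 0.747) and LIN28A at 0.15 (SE 0.17, adjusted p = 0.576). SOX2 was lower in hLLC by log2 -0.62 (SE 0.18, adjusted p = 0.0238), a call that ended in 6 of 16 alternatives (0.00202 to 0.105), including those without hLLC array 2 (log2 -0.59), hLLC array 3 (-0.43) or hALC array 2 (-0.54). HOX genes gave 2 of 23 higher and 3 lower (0.712), with HOXD8 2-fold lower in hLLC, and hedgehog genes 0 of 13 and 3 (0.594; median 0.07, mean -0.33), with HHIP the largest. Senescence and inflammation genes gave 4 of 16 higher and 3 lower (0.474), with IL1B 7.54-fold higher in hLLC and MMP1 4.51-fold lower. Among other cell types, neural genes gave 2 of 9 higher and 4 lower (0.663; PAX6 2.54-fold higher), Sertoli and granulosa genes 3 of 11 and 1 (0.136; INHBB 2.49-fold higher), heart and skeletal muscle 1 of 11 and 0 (0.452; ACTC1 7.11-fold higher), kidney 4 of 9 and 1 (0.123; PAX2 3.23-fold higher) and germ cells 2 of 10 and 0 (0.594; median -0.10, mean 0.66), namely KIT and TFAP2C (6.63-fold higher). KIT and TFAP2C lay near their hiPSC levels in hLLC and were lower in hALC. Endoderm and liver, endothelium and adrenal medulla had 0 members past the threshold by limma (camera adjusted p = 0.663, 0.624 and 0.594), and 0, 2 and 0 at an unadjusted p under 0.05. Their largest differences were TTR at log2 -0.26 (SE 0.15), TEK at -0.59 (SE 0.23) and SLC18A1 at 0.24 (SE 0.17). Adjusted over the list alone these counts were the same, except that 4 neural genes were higher.

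**Figure D3:**
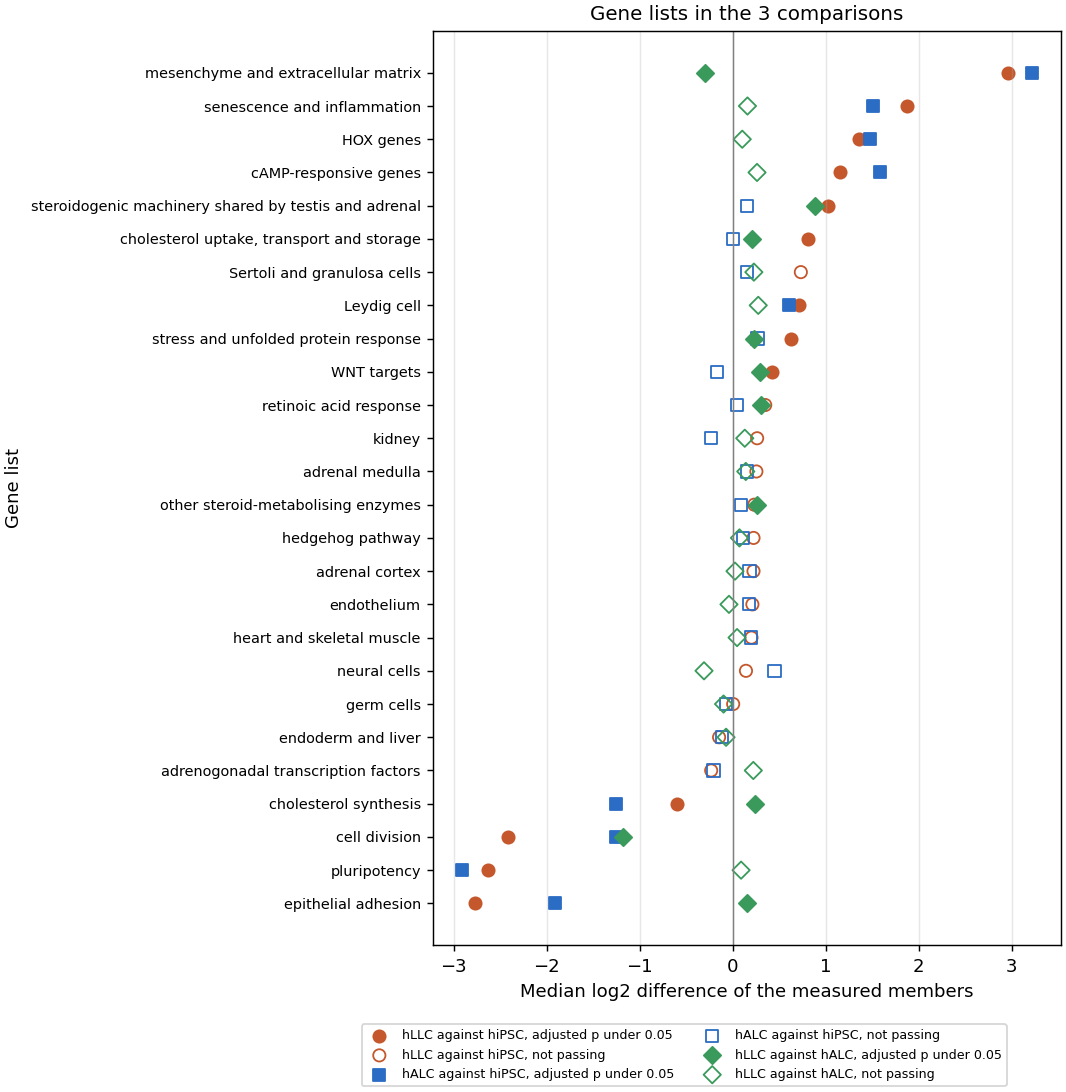
Median log2 difference of the measured members of 26 gene lists (vertical axis) in the 3 comparisons, with circles for hLLC against hiPSC, squares for hALC against hiPSC and diamonds for hLLC against hALC; filled symbols have a camera adjusted p under 0.05. Filled symbols number 13, 9 and 10, from a median of -2.91 for pluripotency in hALC to 3.22 for mesenchyme and extracellular matrix in hALC.

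With an estimated correlation between genes, the camera calls that held were those of pluripotency, cholesterol synthesis, HOX genes, mesenchyme and extracellular matrix and epithelial adhesion against hiPSC in both products, and of senescence and inflammation in hLLC. Between the products 0 of the 10 calls held.

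Changes from hiPSC in hLLC and hALC went largely the same way. Across 17687 genes their log2 changes correlated with Pearson r = 0.89 and Spearman rho = 0.851, and 82.1% had the same sign. Because both comparisons use the same 3 hiPSC arrays, unchanged groups gave r = 0.499, rho = 0.478 and 66.7% in simulations. The covariance was 0.991 against 0.0111 simulated, a difference of 0.98. Higher in both were 3200 genes, where independent lists of these sizes would share 1013, and lower in both were 3788, where they would share 1209. The hiPSC arrays are too few to split, so part of the excess over independent lists may come from the shared arrays. Opposite calls were made for 118 genes, 72 of them higher in hLLC and lower in hALC and 46 the reverse, and all 118 also differed between hLLC and hALC by limma.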

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

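The test of array spread as a covariate, the test of the share of steroidogenic cells, the tests of the trophoblast, decidual and cAMP lists against hiPSC and the choice of the 3 patterns weighed here came after the results were seen. The cartilage, bone, fibroblast, decidual and trophoblast lists were written after the largest changes were seen and before the lists were tested between hLLC and hALC; CGA, TDO2, KRT7, CILP, PRG4 and the named members of these lists lie outside the rule for named genes and were chosen after their values were seen.

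Of the named genes, 13 moved away from hiPSC in opposite directions in the 2 products, each past the threshold in both comparisons. They also passed the direct test, which follows from the opposite calls. Higher in hLLC and lower in hALC were PLCB4 (log2 difference 3.58, hLLC minus hALC), SELENOP (3.16), CYP1B1 (2.92), KRT18 (2.69), SCARB1 (2.59), AXIN2 (1.7), CCL2 (1.56), KRT8 (1.33), HSD17B11 (1.17) and SC5D (1.16). The reverse held for CXCL5 (-4.22), HHIP (-3.87) and CRYBG1 (-3.84). SCARB1, which takes up cholesterol from lipoproteins, changed by log2 1.71 in hLLC and -0.88 in hALC, and HHIP by -0.52 and 3.35. In CCL2 (0.61, adjusted p = 0.0344) and SC5D (0.45, adjusted p = 0.0403) the hLLC side lay near the threshold. Probe sets unnamed here, which the tests of named genes left out, also differed by limma: 1372 of 3739 (36.7%) for hLLC against hiPSC, 1407 (37.6%) for hALC against hiPSC and 330 (8.83%) for hLLC against hALC. Groups of 3 arrays were not tested for single outlying arrays.

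NR5A1 was higher in hALC than in hLLC, while STAR, CYP11A1, HSD3B1, HSD3B2 and CYP17A1 were lower. A smaller share of steroidogenic cells in the hALC cultures, with the same levels in each such cell, would lower all 6 genes together, so it does not by itself account for the NR5A1 difference of log2 -2.42 (95% interval -2.98 to -1.86), a value seen before the explanation was written. For the other 5 genes a smaller share stays open, since NR5A1 RNA may also come from other cells or from a copy introduced to differentiate them, which the labels neither state nor exclude. Array spread as covariate, quantile normalization and median centring each kept the direction and an adjusted p under 0.05 for 6 of the 6 genes. The medians of the hLLC and hALC arrays lay between 7.28 and 7.34, and the smallest of the 6 differences, STAR, was log2 0.88. Refitting such similar arrays could hardly end these calls, so the fits add little against array scaling or spread.

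MMP13, OGN, MGP, COL10A1, CILP (log2 -3.49, hLLC minus hALC) and PRG4 (-2.97) were all higher in hALC. A 2-fold excess of most bone genes in hALC is argued against. Of 8 measured members, 87.5% had an interval below a 2-fold excess in hALC. The list leaned towards hLLC with a camera p of 0.0302, or 0.0662 with an estimated correlation (SPP1 2.29 and ALPL 1.48, but RUNX2 -0.84). A small share of bone-like cells, or a programme of few genes, stays open. Neither need raise most members 2-fold in the whole culture. The medians of the hLLC and hALC arrays lay between 7.28 and 7.34 and their interquartile ranges between 3.08 and 3.25. Differences of that size in the scaling or spread of the deposited values are far below the median excess of 4.28 over the 6 genes. This excess stayed at 4.32 or more in the 3 fits. Refitting such similar arrays could hardly change it, so the fits add little. A fibroblast-like programme may contribute (9 of 15 members higher in hALC and 1 lower, camera p of 2.57e-08, or 0.00154 with an estimated correlation; ASPN -2.79 and MFAP4 -1.92, the latter at a level of 12.62 in hALC), and so may a cartilage-like one (7 of 19 higher and 1 lower, camera p of 0.00103, but 0.0988 with an estimated correlation; EPYC -2.32 and ACAN -1.15, but HAPLN1 1.37, and COL11A1 at 12.79 in hLLC and 12.61 in hALC). Of these lists 1 cartilage gene and 0 bone or fibroblast genes also stand in another list, no sort of the cells is given in the sources used here, and whether the genes come from all hALC or from some of them stays open.

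PRL, CGA, TDO2 and KRT7 rose in hLLC 254-fold, 10.2-fold, 63.8-fold and 15.3-fold over hiPSC, and in hALC 60.3-fold, 1.5-fold, 7.43-fold and 1.91-fold. A 2-fold rise of most trophoblast genes in hLLC is argued against. Over hALC 4 of 21 list members were higher and 0 lower (camera p of 0.0387, or 0.319 with an estimated correlation). Over hiPSC 5 of 21 were higher and 0 lower (0.155, or 0.484). In each comparison 90.5% had an interval below a 2-fold excess. TFAP2C, however, was at 7.99 in hLLC and hiPSC and at 5.26 in hALC, and PAPPA2 rose 3.56-fold over hiPSC. A small share of trophoblast-like cells stays open, since it need not raise most members 2-fold in the whole culture. A 2-fold excess of most decidual stroma genes over hALC is argued against as well. There 3 of 12 members were higher and 2 lower, and 83.3% were so bounded (camera p of 0.49). PRLR was at 7.45 in hLLC and 9.28 in hALC, but DIO2 was 4.46-fold and WNT4 2.28-fold higher in hLLC. PRL and TDO2 are not members, so the list cannot exclude a decidual stroma-like programme of few genes behind their excess over hALC. Such a programme also stays open for the rise over hiPSC, which hALC shared in part (6 of 12 higher and 2 lower, 66.7% bounded, camera p of 0.0754). A cAMP-type response stays open as a candidate explanation, since its list gave a camera p of 8.63e-04 against hiPSC (but 0.201 with an estimated correlation). The cAMP list rose over hiPSC in hALC too, with 11 of 15 higher and 2 lower. Its median log2 change was 1.59 in hALC and 1.15 in hLLC, so the rise was not particular to hLLC. Against hALC the camera p was 0.568 with 73.3% of members bounded, short of the share set for excluding it. Of the trophoblast list 2 members, and of the decidual list 3, also stand in other lists, and a difference between the 2 kinds of cell, which the design names, was not tested further.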

How the results depend on the processing

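The fit with array spread as a covariate was chosen after seeing the data, and the other alternatives were planned. Counts of differing genes stayed within 1.5 times of those reported under all alternatives run, for hLLC against hiPSC from 7729 without the dimmest genes to 9734 with array weights, for hALC against hiPSC from 7376 to 9741 in the same settings, and for hLLC against hALC from 2773 without hALC array 3 to 4539 with array weights. Over all probe sets, which outnumber the genes, 10357, 10148 and 3954 probe sets differed. The balance of directions between hLLC and hALC depended on scaling. It was 1843 higher and 1813 lower in hLLC in the main fit, and 1543 and 2077 with median centring. Leaving out single arrays gave 8000 to 9057, 7911 to 8254 and 2773 to 3664 genes, and 13 to 14, 9 to 9 and 8 to 10 lists. A tested 2-fold threshold, which is stricter by construction, left 2070, 1969 and 265 genes in place of 3556, 3459 and 914. Lists passing numbered 6, 5 and 0 with an estimated correlation, which camera also tests with fewer degrees of freedom. For WNT targets and retinoic acid response the estimates, -0.0309 and -0.0483, lay below the preset 0.01. A higher correlation among their own genes therefore cannot account for their lost calls. For these calls the camera p before adjustment stayed under 0.05. WNT targets gave 0.0173 between the products and 0.0298 for hLLC against hiPSC, and retinoic acid response gave 0.0392 between the products. The adjustment runs over all lists, so it also depends on lists with higher estimates, such as cell division (0.324). How far this adjustment and the fewer degrees of freedom each contributed was not tested. For the other lists the cause of a lost call was not tested. With fry, which does not compare a list with other genes, 24, 22 and 19 lists passed. The retinoic acid list of hALC against hiPSC turned to a fall with fry (adjusted p = 0.00249), and the cause was not tested. The correlation of the changes was 0.898 without the dimmest genes, and 0.883 to 0.892 without single arrays, and the cause was not tested. Among named genes 5314 results were the same, 10 became significant, 150 lost significance and 0 reversed; among lists the numbers were 1331, 35, 37 and 1, where a change of sign that passed in neither setting was not taken as a reversal. The replicate block gave 9022, 8734 and 3622 genes, of which 8796, 8539 and 3437 were called without it; same-numbered arrays of different kinds had correlations of their deviations from -0.14 to 0.24, and 4 of 9 arrays correlated best with their own number, so the numbers were not taken as pairing. No detection call was used, so how far signal over background limits the dim genes was not tested.

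Of the 10 ways to split the 6 arrays of a comparison, too few for a share under 0.05, 1 gave as many differing genes as the real split in each comparison (8990, 8732 and 3656 against at most 0 in the others), and 1 as many at least 2-fold (3556, 3459 and 914 against 0). For lists, 1, 3 and 1 splits gave as many (13 against 12 at most, 9 against 9, and 10 against 3). Each of the other splits mixes the 2 kinds of cell, so their difference enters the spread. The design thus made gene counts of 0 there likely, and they do not show what unchanged groups would give.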

Other observations

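The lists of this part were written after the largest changes were seen, and the named members were chosen after their values were seen. Fibroblast genes, which mark the stroma of connective tissue, were higher than in hiPSC in 11 of 15 cases in hALC and lower in 2 (median log2 2.41, camera p of 1.31e-06, or 0.00311 with an estimated correlation), and in 8 and 2 cases in hLLC (median 0.46, camera p of 0.0115, or 0.0472). Cartilage genes were higher in 13 of 19 cases in hALC and lower in 1 (median 0.997, camera p of 4.47e-06, or 0.0342), and in 8 and 2 in hLLC (median 0.22, camera p of 0.0201, or 0.216). COL2A1, the main collagen of cartilage, was 2.04-fold higher in hALC (log2 1.03, SE 0.15) and 1.46-fold in hLLC (log2 0.55, SE 0.15). Bone genes gave 1 of 8 higher and 2 lower in hALC (camera p of 0.667) and 3 and 1 in hLLC (0.239). Trophoblast genes gave 5 of 21 higher and 2 lower in hALC (0.793) and 5 and 0 in hLLC (0.155), and decidual genes 5 of 12 and 2 in hALC (0.143) and 6 and 2 in hLLC (0.0754).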
